A study of Mus musculus with 16 samples.

How the data were processed

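Gene expression was measured in regulatory T cells (Treg cells) of C57BL/6 mice on 16 gene arrays, in 4 groups of 4. Per the labels' protocols, CD4+ cells carrying a Foxp3-YFP reporter were sorted from spleen and peripheral lymph nodes and then stimulated for 4 h with plate-bound antibodies to CD3 and CD28. The mice were heterozygous (Atg7+/-) or homozygous (Atg7-/-) for a floxed Atg7 gene deleted by a Cre recombinase expressed with Foxp3. In each genotype 1 group was untreated and 1 had received rapamycin, an inhibitor of the kinase mTOR, injected intraperitoneally at 4 mg per kg each day for 5 days. RNA was purified on columns with DNase digestion, 1 to 5 ng of total RNA was amplified as cDNA with a NuGEN whole-transcript kit, and the cDNA was labelled with biotin, per the labels' protocols.

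The deposited values are log2 signals, 1 per probe set and array, for 41345 probe sets. RMA (background correction, quantile normalization and probe summarization) and Partek 6.6 are named in the submitters' processing notes, without their order or settings. The base of the logarithm is not written in the file. It was taken as 2, the base RMA uses, and every fold given here rests on that; the values run from 1.4886 to 13.4975. The genome build and the annotation version are not given in the sources used here, nor are hybridization dates or other batch labels. No value column was left unmapped to a sample. Arrays give no read depth, so the number of arrays limits the precision.

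Each probe set was named through GEO's platform annotation. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 were not listed there. Of the probe sets with 1 symbol, 23328 matched a current mouse gene record by Entrez identifier, all with the same symbol. They stood for 22180 genes, of which 1082 had more than 1 probe set. For those the probe set with the highest mean over the 16 arrays was used. Genes were tested where the highest of the 4 group means exceeded 3.549, the 30th percentile of all values, which kept 16760 genes and left out 5420. Near-identical genes such as Hspa1a and Hspa1b, histone genes, ribosomal protein genes and receptor gene families can share probes, and their values are uncertain for that reason.

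A linear model with 1 mean per group was fitted to all 16 arrays in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes without trend or robust options; 12 residual and 5.64 prior degrees of freedom). The contrasts were Atg7-/- over Atg7+/- without and with rapamycin, rapamycin over untreated in each genotype, and the difference between the rapamycin effects. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 16760 genes, and a gene was called at an adjusted p under 0.05. Standard errors (SE) are those of the moderated fit, and a group's SD is over its 4 arrays. The fit takes 1 spread per gene for all 4 groups, although the groups' spreads differed. The root mean square deviation of an array from its group mean was 0.1422 to 0.1564 in untreated Atg7+/- cells. It was 0.159 to 0.2422 in rapamycin Atg7-/- cells, so an SE can be too small for comparisons with that group. The labels do not say which replicates came from separate mice, so p-values measure only the spread between these samples, which may be technical in part.

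Gene lists for pathways, T cell states and markers of other cell types, 34 in all, were fixed before the data were examined. No gene matched from the conventional T cell marker list was left out as dim in these Treg cells. The filter on dim genes takes the highest group mean, so passing it does not show that Treg cells express a gene. Shifts of that list were not taken as a measure of the share of conventional T cells. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 34 lists within a comparison, and again with a correlation estimated from the data. The same lists were tested with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. Counts of called members are given over all genes tested and adjusted over the list alone. No list call held with an estimated correlation in any comparison, where the smallest adjusted p was 0.0687; fry called 7 lists between untreated genotypes, 11 and 14 for rapamycin in Atg7+/- and Atg7-/- cells, and 5 between genotypes under rapamycin.

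Named genes were chosen by a rule fixed before the data were examined. It takes Atg7, Foxp3 and Myc always, and the 8 genes that rose and the 8 that fell most among called genes with no overlap between the groups' arrays, leaving out predicted genes, clones and antigen receptor segments. It also takes up to 4 called members with the largest change in each list described or, where none was called, up to 2 with the smallest p. For the difference of the rapamycin effects the condition on overlap was dropped, and with fewer than 3 genes called the 3 with the smallest p in each direction are given as values. Members that moved against the rest of their list were named after their values were seen, namely Lta, Fgl2, Pdcd1, Cd69, Atg9a, Mcm7, Actn1, Eif4a1, Wars, Vldlr and Rpl11, and Nt5e in the rapamycin comparison.

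The fit and camera were tested on simulated data with the real genes' means and spreads, in which 200 of the 16760 genes were changed. Genes were drawn independently and with equal spread in all groups, so correlated genes and unequal spreads were not tested. The changed genes were also a smaller share than the 14.1% and 20% of genes called for rapamycin, and recovery there may differ. A log2 change of 1 was recovered for 95%, 92%, 94% and 96% of such genes between untreated genotypes, for rapamycin in Atg7+/- cells, for rapamycin in Atg7-/- cells and between genotypes under rapamycin. A log2 change of 0.5 was recovered for 52%, 53%, 55% and 58%, and false calls were 8.12%, 3.97%, 3.87% and 4.94% of all calls. Alternatives were other rules for several probe sets per gene, other filters on dim genes, quantile normalization, median centring, other variance models, array weights, fits on only the groups compared, stricter thresholds, replicate number as a block and leaving out each array in turn. Chosen after the data were seen were leaving out 2 outlying arrays, leaving out receptor and small RNA genes, a receptor gene covariate and removing the trend with gene length. Probe sets with several symbols or none were left out of the comparisons.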

Results

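Atg7 encodes the E1-like enzyme that drives the conjugation steps of autophagy, the pathway that delivers cell contents to the lysosome. The series compared stimulated Treg cells that keep 1 intact copy of Atg7 with Treg cells whose copies are both floxed, each from untreated mice and from mice given rapamycin. Its title places the work in the role of autophagy in the stability and metabolism of Treg cells, CD4+ T cells that restrain immune responses. Each of the 4 groups held 4 arrays. Pearson correlations over the log2 values of the genes tested were 0.9733 to 0.9939 between arrays and 0.9801 to 0.9939 within groups. No 2 arrays were identical, and array medians over all probe sets lay between 4.411 and 4.632. The first principal component held 34.5% of the variance and separated rapamycin from untreated arrays, and the second, with 14.57%, separated the genotypes. Rapamycin Atg7-/- replicate 3 stood apart from its group, with a score of -29.83 on the second component against -12.88 to -7.567 for the other arrays of that group.

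**Figure D1:**
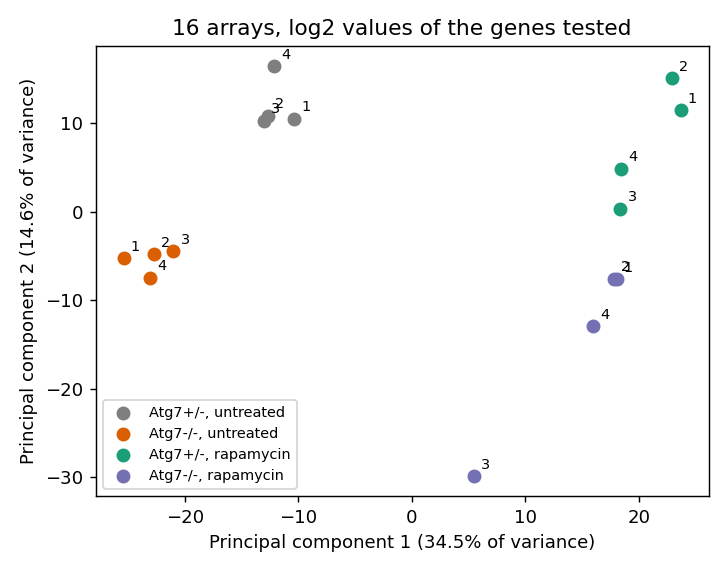
Scores of the 16 arrays on the first 2 principal components of the log2 values of the genes tested, 1 point per array, coloured by genotype and treatment. Untreated arrays score from -25.4 to -10.41 on the first component and rapamycin arrays from 5.425 to 23.67, where 5.425 is rapamycin Atg7-/- replicate 3.

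Atg7 itself was measured by 1 probe set, 17461897. Its log2 value was 6.66 ± 0.0598 in untreated Atg7+/- cells and 6.38 ± 0.24 in untreated Atg7-/- cells (SD, n = 4 each), a log2 difference of -0.28 (SE 0.134, limma adjusted p = 0.299). Under rapamycin the values were 6.79 ± 0.0781 and 6.48 ± 0.314, a difference of -0.30 (SE 0.134, limma adjusted p = 0.232). The deleted part of the gene is not given in the labels and the probe set may lie outside it, so these values check nothing about the genotype labels.

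The comparison of untreated cells asks how loss of Atg7 alters gene expression in stimulated Treg cells. Untreated Atg7-/- Treg cells expressed several effector cytokine genes more highly than Atg7+/- cells. Il4, the signature cytokine of T helper 2 cells, rose 5.58-fold, from a log2 value of 6.34 ± 0.159 to 8.82 ± 0.454 (SD, n = 4 each; log2 fold change 2.48, SE 0.253, limma adjusted p = 0.000121). Ifng, the signature cytokine of T helper 1 cells, rose 4.27-fold (2.09, SE 0.392, adjusted p = 0.00622), and Il13, another T helper 2 cytokine, 3.23-fold (1.69, SE 0.3, adjusted p = 0.0043). Foxp3, the transcription factor that defines Treg cells, was 1.32-fold lower, at 10.86 ± 0.222 against 11.26 ± 0.0376 (-0.40, SE 0.101, adjusted p = 0.0355). Hspa1a and Hspa1b, near-identical genes for inducible heat-shock protein 70 whose probes may be shared, fell 6.41-fold and 5.38-fold (-2.68, SE 0.513, adjusted p = 0.00732, and -2.43, SE 0.547, adjusted p = 0.0198).

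Among the other genes that rose most were Ccl3, a chemokine gene (log2 fold change 1.76), Gzmb, which encodes the cytotoxic protease granzyme B (1.65), and Nuf2, a kinetochore component (1.71). The histone genes H1f5 and H2ac15, members of families of near-identical copies, rose by 1.84 and 1.54. The genes that fell most also included Vps37b, a subunit of the ESCRT-I sorting complex (-1.43), and Ptpn13, a tyrosine phosphatase (-1.10). Pde2a, a phosphodiesterase, fell by 1.11 and Gucy1a1, a guanylate cyclase subunit, by 1.10. Cxcr4, a chemokine receptor, fell by 1.01 and Rgs2, a regulator of G protein signalling, by 0.99. Myc, a transcription factor of cell growth, had a log2 fold change of -0.09 (SE 0.0908, adjusted p = 0.689).

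Of 23 effector cytokine genes 10 rose, and 1 fell, Lta, which encodes lymphotoxin alpha (-0.55). Adjusted over the list alone 14 rose and 1 fell, and the list's median was 0.79 (camera adjusted p = 3.09e-09; adjusted p = 0.131 with an estimated correlation). Of 39 cell cycle genes 15 rose and none fell, or 22 and none adjusted over the list alone, with a median of 0.38 (camera adjusted p = 1.03e-15; adjusted p = 0.0687 with an estimated correlation). They included the proliferation marker Mki67 (1.45), the mitotic kinesin Kif11 (1.27), topoisomerase Top2a (1.26) and cyclin Ccna2 (1.20). In the list of effector Treg genes 7 of 25 rose and 2 fell, or 11 and 4 adjusted over the list alone. The risers were led by the calcium-binding protein genes S100a6 (1.40) and S100a4 (1.18), the inhibitory receptor Havcr2 (1.25) and the galectin Lgals1 (1.12). Those that fell were Fgl2, a secreted suppressive protein (-0.78), and the inhibitory receptor Pdcd1 (-0.70); the list as a whole was not called (median 0.04, camera adjusted p = 0.0578).

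Of 26 Treg signature genes 2 rose, Gzmb and Lad1 (0.57), and 3 fell, Foxp3, the transcription factor Plagl1 (-0.73) and Nt5e, which encodes the ectoenzyme CD73 (-0.67). Adjusted over the list alone 2 rose and 4 fell, and the list was not called (median -0.07, camera adjusted p = 0.0611). Markers of conventional T cells had a median of 0.21 over 11 genes (camera adjusted p = 0.0388; adjusted p = 0.617 with an estimated correlation). Among them 1 rose, Themis, a T cell receptor signalling protein (1.36), and 1 fell, Nt5e; adjusted over the list alone the counts were 3 and 1. Without 1 of untreated Atg7+/- replicate 2 and Atg7-/- replicates 1, 2 and 3 that list's call was lost, at adjusted p = 0.0709, 0.0777, 0.0934 and 0.0574, as it was with quantile normalization (0.0596). By fry the conventional T cell list was not called (adjusted p = 0.163). Markers of CD8 T and NK cells were not called as a list (10 genes, median 0.0872, camera adjusted p = 0.127), although Gzma, another granzyme (1.14), and Nkg7, a cytotoxic granule protein (0.86), rose, both also adjusted over the list alone. The lists for neutrophils, plasma cells, macrophages, erythroid cells, B cells, dendritic cells and stromal cells were not called, at camera adjusted p = 0.161 to 0.642.

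Lists of mitochondrial and growth-related genes had positive medians with few single calls. Fry did not call the mitochondrial ribosome (adjusted p = 0.0525), oxidative stress (0.0525) or proteasome (0.0718) lists. Of 71 mitochondrial ribosome genes 4 rose and 1 fell, Mrpl27 (-0.78), or 18 and 1 adjusted over the list alone (median 0.22, camera adjusted p = 1.57e-09; adjusted p = 0.392 with an estimated correlation). Of 53 oxidative phosphorylation genes 2 rose, the complex I subunit Ndufa8 (0.41) and the cytochrome oxidase subunit Cox7a2 (0.30), or 7 adjusted over the list alone (median 0.16, camera adjusted p = 8.07e-09; adjusted p = 0.392 with an estimated correlation). Of 50 genes of Myc-linked ribosome biogenesis 3 rose, Wdr12 (0.34), Ddx18 (0.34) and Dkc1 (0.30), or 17 adjusted over the list alone (median 0.18, camera adjusted p = 2.17e-10; adjusted p = 0.392 with an estimated correlation). Nqo1 and Srxn1, antioxidant enzymes of the oxidative stress list, rose by 1.54 and 0.65, and 3 of its 19 genes rose adjusted over the list alone (median 0.20, camera adjusted p = 0.00146; adjusted p = 0.461 with an estimated correlation). Hk2, a hexokinase that starts glycolysis, rose by 0.49 and was the 1 glycolysis gene called of 20, also adjusted over the list alone (median 0.15, camera adjusted p = 0.0101; adjusted p = 0.392 with an estimated correlation). The proteasome list, with 1 riser of 38, Psmd5 (0.45), or 2 adjusted over the list alone, was called as well (median 0.15, camera adjusted p = 3.59e-05; adjusted p = 0.494 with an estimated correlation). In the amino acid response list 2 of 35 rose, the serine synthesis enzyme Psph (0.45) and the tyrosyl-tRNA synthetase Yars (0.34), or 5 rose and 1 fell adjusted over the list alone (median 0.12, camera adjusted p = 0.0217; adjusted p = 0.392 with an estimated correlation). Without untreated Atg7-/- replicate 2 that list was not called (adjusted p = 0.0842).

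Lists of early T cell receptor response, resting T cells and autophagy had negative medians. Fry called none of these lists (adjusted p = 0.121, 0.133 and 0.119, in that order). Of 29 early response genes 2 fell, the transcription factor Fosb (-0.85) and the surface protein Cd83 (-0.43), or 4 adjusted over the list alone (median -0.16, or -0.089 without untreated Atg7-/- replicate 4; camera adjusted p = 0.00017; adjusted p = 0.392 with an estimated correlation). Ccr7, the receptor that brings T cells into lymph nodes, fell by 0.82 as the 1 called gene of 19 in the resting list, where 1 rose and 4 fell adjusted over the list alone (median -0.17, camera adjusted p = 0.000212; adjusted p = 0.392 with an estimated correlation). Rb1cc1, a subunit of the kinase complex that starts autophagy, fell by 0.50 as the 1 called gene of 35 in the autophagy list, where 5 fell adjusted over the list alone (median -0.12, camera adjusted p = 0.000255; adjusted p = 0.392 with an estimated correlation).

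Over all 16760 genes limma called 527 between untreated genotypes, 294 higher and 233 lower in Atg7-/- cells, of which 32 and 8 changed at least 2-fold. The 4 arrays of each genotype did not overlap for 14.1% of genes, where chance gives 2.86%. The count was 295, 333, 319 and 282 without untreated Atg7+/- replicates 1 to 4, 299 and 322 without untreated Atg7-/- replicates 1 and 4, and 318 with each array centred on its median (165 higher and 153 lower). The balance of higher and lower genes turned to 282 and 303 with the trend on gene length removed and to 192 and 210 without untreated Atg7-/- replicate 2, and was 215 and 215 with all probe sets counted. Of the 50 called genes named here, 17 lost the call without some 1 of the untreated arrays: Foxp3 without any Atg7+/- array or Atg7-/- replicate 1, 3 or 4 (adjusted p up to 0.091), and H1f5, Hspa1b, Rgs2, S100a4, Gzma, Ndufa8, Cox7a2, Wdr12, Ddx18, Dkc1, Fosb, Cd83, Lta, Psph, Yars and Psmd5 (up to 0.0557, 0.07, 0.109, 0.0652, 0.0588, 0.125, 0.0804, 0.0836, 0.113, 0.11, 0.0647, 0.0729, 0.0935, 0.107, 0.109 and 0.071), with Rgs2, Ndufa8, Dkc1 and Yars also losing it without rapamycin Atg7+/- replicate 4, Ndufa8 without replicate 1 and Dkc1 without replicate 2 of that group.

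**Figure D2:**
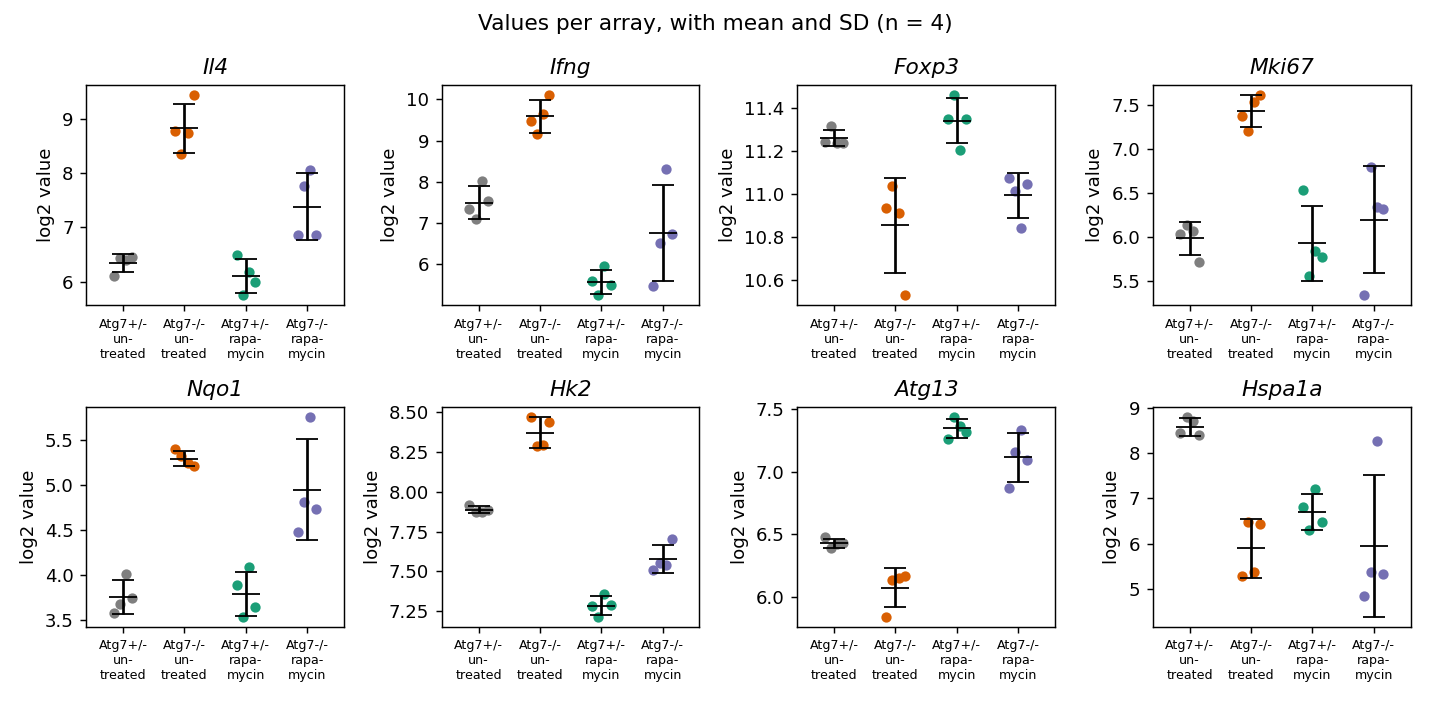
Log2 values of 8 genes on each of the 16 arrays, in 4 groups of 4, with points for arrays and bars for the mean and SD. Il4 and Ifng are highest in untreated Atg7-/- cells, Foxp3 means are 10.86 and 10.99 in the Atg7-/- groups and 11.26 and 11.34 in the Atg7+/- groups, and in rapamycin Atg7-/- cells 1 array, replicate 3, stands above the others for Hspa1a.

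Rapamycin in Atg7+/- mice addressed how treatment of the mice alters gene expression in Treg cells that keep 1 intact copy of Atg7. The controls are labelled untreated and mTOR activity was not measured. Effects of the injections, or of the drug on other cells, cannot be told apart from mTOR inhibition in Treg cells. Cytokine genes fell: Il13 fell 4.71-fold (log2 fold change -2.24, SE 0.3, limma adjusted p = 0.000156), Il3, a haematopoietic growth factor gene, 4.04-fold (-2.01, SE 0.37, adjusted p = 0.00201) and Ifng 3.79-fold (-1.92, SE 0.392, adjusted p = 0.00409). Xcl1, a chemokine gene, fell 3.59-fold (-1.84, SE 0.226, adjusted p = 7.65e-05). Hk2 fell 1.52-fold (-0.60, adjusted p = 9.46e-05), while Atg13, a subunit of the kinase complex that starts autophagy, rose 1.88-fold (0.91, adjusted p = 2.79e-05), with n = 4 in each group. Foxp3, Myc and Atg7 had log2 fold changes of 0.08, 0.16 and 0.13 (adjusted p = 0.635, 0.258 and 0.571).

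The genes that rose most were mostly odorant receptor and microRNA genes. They were the receptor genes Olfr726 (2.44, 5.44-fold), Olfr584 (1.93) and Olfr1219 (1.78), the microRNA genes Mir210 (1.75), Mir188 (1.75), Mir467c (1.70) and Mir98 (1.70), and Ssxb8 (1.56). Olfr310 (-2.32), Mir297a-4 (-1.93) and Rnu3a, a small nucleolar RNA gene (-1.66), were among those that fell most, with Hspa1a (-1.88). Of 289 olfactory and vomeronasal receptor genes tested, 19.7% were called, 36 higher and 21 lower, against 14% of the other genes and against 0.692% of receptor genes between untreated genotypes. Among 262 microRNA genes 26.7% were called. The absolute log2 fold change of receptor genes had a 95th percentile of 0.921, and 136 of the 2313 called genes of other classes lay beyond it.

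Of 23 effector cytokine genes 13 fell and none rose, or 15 and none adjusted over the list alone (median -0.80, camera adjusted p = 1.62e-09; adjusted p = 0.155 with an estimated correlation). Of 25 effector Treg genes 12 fell and none rose, or 13 and none adjusted over the list alone (median -0.28, camera adjusted p = 6.16e-06; adjusted p = 0.506 with an estimated correlation). They were led by S100a4 (-1.43), the chemokine receptor Ccr2 (-0.99), S100a6 (-0.97) and Klrg1, a receptor of differentiated effector cells (-0.97). In the early T cell receptor response list 10 of 29 fell, among them Nfkbie, an inhibitor of NF-kappaB (-0.94), and 1 rose, the activation marker Cd69 (0.30). Adjusted over the list alone 14 fell and 1 rose (median -0.29, or from -0.368 to -0.192 over its alternatives, with camera adjusted p = 0.000133, or 0.506 with an estimated correlation). Of 11 conventional T cell markers 6 fell, including Thy1 (-0.88), the costimulatory ligand Cd40lg (-0.75) and the signalling adaptor Lat (-0.69), and the 6 also fell adjusted over the list alone (median -0.55, camera adjusted p = 0.00178, or 0.506 with an estimated correlation). Genes of this list, such as Lat, are also expressed in these Treg cells. Cell cycle genes were not called as a list (camera adjusted p = 0.691), nor were Treg signature genes (0.233).

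Of 20 glycolysis genes 11 fell and none rose, with the same counts adjusted over the list alone (median -0.34, camera adjusted p = 4.06e-06; adjusted p = 0.155 with an estimated correlation). The lactate transporter Slc16a1 (-0.66), Hk2, pyruvate kinase Pkm (-0.60) and the hexokinase Hk1 (-0.58) led them. Of 35 autophagy genes 9 rose and 1 fell, Atg9a (-0.31), or 12 and 1 adjusted over the list alone (median 0.13, or 0.0852 with median centring; camera adjusted p = 0.000362; adjusted p = 0.506 with an estimated correlation). Besides Atg13, the kinase complex subunits Rb1cc1 (0.74) and Ulk2 (0.65) and the lipid kinase Pik3c3 (0.51) rose. No named member of these 2 lists changed by more than the 0.921 given above for receptor genes. Of 50 genes of Myc-linked ribosome biogenesis 6 fell, among them Utp4 (-0.46) and Nop2 (-0.42), also 6 adjusted over the list alone (median -0.16, camera adjusted p = 0.000126; adjusted p = 0.637 with an estimated correlation).

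Of 60 cytosolic ribosome genes 7 rose and 3 fell, with the same counts adjusted over the list alone (median 0.064, camera adjusted p = 0.00308; adjusted p = 0.506 with an estimated correlation). That median was 0.0234 with quantile normalization, 0.0205 with each array centred on its median and 0.104 with the trend on gene length removed. Rplp0 rose by 0.55, a direction that turned to -0.00895 with the mean of its probe sets in place of the brightest, and Rps15 (-0.74), Rpl26 (-0.48) and Rpl11 (-0.44) fell. In the amino acid response list 9 of 35 fell, among them the serine synthesis enzyme Psat1 (-0.54), and 1 rose, the lipoprotein receptor Vldlr (0.39), also adjusted over the list alone (median -0.15, camera adjusted p = 0.0468; adjusted p = 0.535 with an estimated correlation). The lysosome list held 5 fallers of 30, led by the protease Ctsb (-0.60) and the proton pump subunit Atp6v1a (-0.59), or 6 adjusted over the list alone (median -0.16, camera adjusted p = 0.0333; adjusted p = 0.802 with an estimated correlation). In the interferon list 3 of 22 genes fell, among them Ifit3 (-0.63), or 4 adjusted over the list alone (median -0.26, camera adjusted p = 0.0177; adjusted p = 0.802 with an estimated correlation). In the cholesterol synthesis list 2 of 19 fell, the enzyme Hsd17b7 (-0.70) and the regulator Srebf2 (-0.51), with the same count adjusted over the list alone (median -0.31, camera adjusted p = 0.032; adjusted p = 0.802 with an estimated correlation). Without rapamycin Atg7+/- replicate 2 the last 4 of these lists lost the call, at adjusted p = 0.0673, 0.0898, 0.0519 and 0.0639 in the order given, as they did without replicate 1 for the first 3 of them (0.0666, 0.145 and 0.0666) and some lost it without untreated Atg7+/- replicate 1, 2 or 3, untreated Atg7-/- replicate 1, rapamycin Atg7+/- replicate 4 or rapamycin Atg7-/- replicate 1 (up to 0.0885). Centring each array on its median ended the calls of the amino acid (0.059), lysosome (0.0629) and cholesterol synthesis (0.052) lists. The amino acid call also ended with quantile normalization (0.105), without the 2 outlying arrays (0.0509), without receptor and small RNA genes (0.0526) and with the trend on gene length removed (0.0573). By fry the lysosome (adjusted p = 0.136), interferon (0.112) and cholesterol synthesis (0.123) lists were not called.

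In total limma called 2370 genes for rapamycin in Atg7+/- cells, 1011 higher and 1359 lower, of which 53 and 53 changed at least 2-fold. With each array centred on its median the split was 668 higher and 1448 lower, and it turned to 1260 and 1173 with the trend on gene length removed and to 1923 and 1752 with all probe sets counted. The arrays of the compared groups did not overlap for 22.7% of genes, where chance gives 2.86%. Without rapamycin Atg7+/- replicate 2 the count was 1554. Of the 52 called genes named here or further on, 7 lost the call without some 1 array of these groups: Hspa1a without replicate 2 of either group (adjusted p up to 0.061), Ccr2 without untreated replicate 2 or 3 (up to 0.0547), Klrg1 without those or rapamycin replicate 2 (up to 0.0585), and Rps15, Atg9a, Rpl11 and Vldlr without any of 5 or 6 arrays, among them untreated replicate 1 and rapamycin replicate 1 (up to 0.112, 0.0879, 0.115 and 0.0969).

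**Figure D3:**
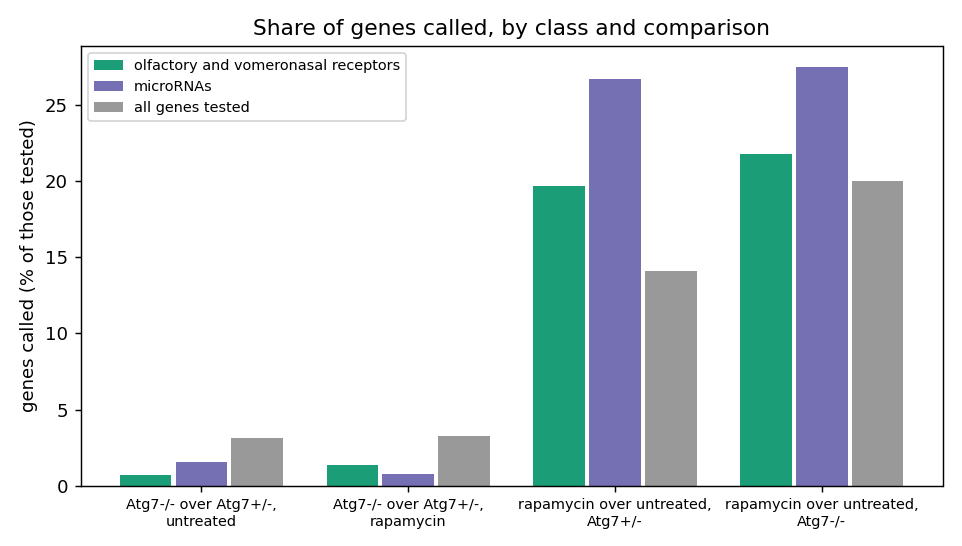
Percent of genes called in each of 4 comparisons, for olfactory and vomeronasal receptor genes, microRNA genes and all genes tested. Receptor genes are called at 19.7% and 21.8% in the rapamycin comparisons and at 0.692% and 1.38% between genotypes.

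Rapamycin in Atg7-/- mice addressed what the same treatment of the mice does once Atg7 is lost. Gzmb fell 7.59-fold, from 8.73 ± 0.149 to 5.81 ± 0.958 (SD, n = 4 each, log2 fold change -2.92, SE 0.299, limma adjusted p = 7.41e-06). That SE rests on 1 spread shared by all groups, while the rapamycin arrays varied far more than the untreated ones. Il13 fell 7.27-fold (-2.86, adjusted p = 9.57e-06), Ifng 7.12-fold (-2.83, SE 0.392, adjusted p = 0.000117) and Il5, a T helper 2 cytokine, 4.72-fold (-2.24, adjusted p = 1.17e-05). S100a4 fell 4.87-fold (-2.29, adjusted p = 2.13e-05), H2ac15 4.37-fold (-2.13, adjusted p = 7.25e-06) and Glrx, a glutaredoxin, 3.78-fold (-1.92, adjusted p = 6.54e-05). Atg13 rose 2.05-fold (1.04, adjusted p = 4.61e-06). Klhl24, a ubiquitin ligase adaptor, rose 3.47-fold (1.80, SE 0.134, adjusted p = 7.45e-07), and Hapln1, an extracellular matrix link protein, 3.55-fold (1.83, adjusted p = 0.000434). Foxp3, Myc and Atg7 had log2 fold changes of 0.14, 0.22 and 0.10 (adjusted p = 0.346, 0.0989 and 0.635).

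The remaining genes that rose most were Olfr726 (2.51, 5.7-fold), Mir188 (1.95), Mir210 (1.92), Ssxb8 (1.72), Olfr584 (1.61) and Olfr259 (1.56), and Mir297a-4 (-2.76) was among those that fell most. Receptor genes were called at 21.8%, 30 higher and 33 lower, against 19.9% of the other genes, and microRNA genes at 27.5%. The 95th percentile of their absolute log2 fold change was 0.994, and 138 of the 3284 called genes of other classes lay beyond it.

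Of 25 effector Treg genes 16 fell and none rose, or 17 fell and 1 rose adjusted over the list alone (median -0.50, camera adjusted p = 8.71e-10; adjusted p = 0.234 with an estimated correlation). S100a6 (-1.67), Klrg1 (-1.61) and Ccr2 (-1.41) were among them. Of 23 effector cytokine genes 15 fell and none rose, or 16 and none adjusted over the list alone (median -0.86, camera adjusted p = 5.23e-09; adjusted p = 0.156 with an estimated correlation). Of 39 cell cycle genes 18 fell, including Birc5, a component of the chromosomal passenger complex (-1.43), Mki67 (-1.24), Kif11 (-0.97) and Top2a (-0.92). In that list 1 rose, the replication helicase subunit Mcm7 (0.57), and adjusted over the list alone 22 fell and 2 rose (median -0.38, camera adjusted p = 2.7e-05; adjusted p = 0.234 with an estimated correlation). Of 19 resting T cell genes 7 rose, led by the receptor Il7r (0.96) and the transcription factors Klf2 (0.74) and Bach2 (0.71), and 1 fell, Actn1 (-0.49). Adjusted over the list alone 10 rose and 1 fell (median 0.38, or 0.225 without the 2 outlying arrays; camera adjusted p = 0.00125; adjusted p = 0.518 with an estimated correlation). Of 11 conventional T cell markers 6 fell, including Themis (-1.34) and Thy1 (-1.01), and 1 rose, Nt5e (0.39), with the same counts adjusted over the list alone (median -0.39, camera adjusted p = 0.00278; adjusted p = 0.518 with an estimated correlation). Treg signature genes were not called as a list (camera adjusted p = 0.132).

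Of 35 autophagy genes 15 rose and none fell, with the same counts adjusted over the list alone (median 0.23, camera adjusted p = 2.1e-06; adjusted p = 0.234 with an estimated correlation). With Atg13 they included Ulk2 (1.01), Rb1cc1 (0.93) and Map1lc3b, the protein that marks autophagosomes (0.68). The list's median was 0.126 without rapamycin Atg7-/- replicate 2. Atg13 and Ulk2 exceeded the 0.994 given above for receptor genes and the other 2 did not. Of 20 glycolysis genes 12 fell and none rose, or 14 and none adjusted over the list alone (median -0.36, camera adjusted p = 2.1e-06; adjusted p = 0.156 with an estimated correlation). Hk2 (-0.80), Slc16a1 (-0.72), Pkm (-0.65) and the lactate transporter Slc16a3 (-0.56) led them, all within the receptor value. Of 35 amino acid response genes 12 fell, among them Psat1 (-0.54) and Yars (-0.51), and 1 rose, the tryptophanyl-tRNA synthetase Wars (0.29). Adjusted over the list alone 16 fell and 1 rose (median -0.26, camera adjusted p = 0.00125; adjusted p = 0.234 with an estimated correlation).

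Of 60 cytosolic ribosome genes 13 rose and 3 fell, Rps15 (-1.06), Rpl11 (-0.55) and Rpl26 (-0.41), or 16 and 3 adjusted over the list alone (median 0.14, camera adjusted p = 2.7e-05; adjusted p = 0.234 with an estimated correlation). Rplp0 led the risers at 0.72, a call lost with the mean of its probe sets in place of the brightest. Of 53 oxidative phosphorylation genes 12 rose, among them the complex I subunit Ndufb3 (0.62), also 12 adjusted over the list alone (median 0.0902, or 0.0452 without rapamycin Atg7-/- replicate 3; camera adjusted p = 0.00227; adjusted p = 0.708 with an estimated correlation). Of 71 mitochondrial ribosome genes 14 rose, led by Mrpl27 (0.89), and 3 fell, with the same counts adjusted over the list alone (median 0.0817, camera adjusted p = 0.0104; adjusted p = 0.708 with an estimated correlation). That list's median was 0.0113 without rapamycin Atg7-/- replicate 3, which ended the call (adjusted p = 0.188). Fry called neither the mitochondrial ribosome list (adjusted p = 0.266) nor the oxidative phosphorylation list (0.126). Of 50 genes of Myc-linked ribosome biogenesis 13 fell, led by Utp4 (-0.48) and Nop2 (-0.47), and 1 rose, the translation factor Eif4a1 (0.42, or 0.13 and not called with the mean of its probe sets), or 15 and 1 adjusted over the list alone (median -0.15, camera adjusted p = 0.00675; adjusted p = 0.708 with an estimated correlation). Without rapamycin Atg7-/- replicate 2 that call was lost (median -0.0901, adjusted p = 0.069).

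For rapamycin in Atg7-/- cells limma called 3347 genes, 1480 higher and 1867 lower, of which 73 and 75 changed at least 2-fold. The split was 1357 and 1372 with each array centred on its median, and it turned to 1799 and 1608 with the trend on gene length removed. The arrays of the compared groups did not overlap for 20.4% of genes, where chance gives 2.86%. Of the 58 called genes named here or further on, 4 lost the call without some 1 array of these groups: Rpl26 without rapamycin replicate 2 (adjusted p = 0.058), and Nt5e, Eif4a1 and Wars without any of 5 or 6 arrays, among them untreated replicate 4 and rapamycin replicates 2 and 3 (up to 0.112, 0.0866 and 0.102).

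The difference between the rapamycin effects asks whether the drug acts otherwise once Atg7 is lost. In limma no gene was called for it, with 1052 genes at an unadjusted p under 0.05, a smallest adjusted p of 0.139 and no call in the unmoderated linear model either. This contrast has a larger SE than either rapamycin effect, and its recovery of known changes was not simulated. The lack of calls therefore does not show that the drug acts alike in both genotypes. Among the genes with the smallest p, the values lower in Atg7-/- cells were -2.38 for Gzmb (SE 0.423, adjusted p = 0.139), -1.07 for Morrbid, a long noncoding RNA gene (adjusted p = 0.139), and -0.88 for the histone gene H2ac10 (adjusted p = 0.232). Higher values were 0.70 for Trappc6a, a vesicle tethering subunit (SE 0.126, adjusted p = 0.139), 0.69 for the nuclear envelope gene Nemp1 (0.35 with the mean of its probe sets) and 1.01 for the dynein gene Dnah7a (adjusted p = 0.139 each). For Foxp3, Myc and Atg7 the differences were 0.06, 0.06 and -0.03 (adjusted p = 0.967, 0.964 and 0.987). Without rapamycin Atg7-/- replicate 2 Gzmb was the 1 gene called, at -2.68 (adjusted p = 0.0242).

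As a list, the 39 cell cycle genes had a median difference of -0.29, where rapamycin's effect was lower in Atg7-/- cells (camera adjusted p = 5.1e-13; adjusted p = 0.131 with an estimated correlation). No single member was called over all genes and 11 were lower adjusted over the list alone, with values of -0.70 for the microtubule regulator Stmn1 and -0.76 for Birc5 (adjusted p = 0.349 each over all genes).

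Under rapamycin, the genotype comparison asks which differences between Atg7-/- and Atg7+/- cells are present with the drug. Il3 was 4.49-fold higher in Atg7-/- cells (log2 fold change 2.17, SE 0.37, limma adjusted p = 0.00632, n = 4 each), Ccl3 2.52-fold (1.33, adjusted p = 0.00896) and Il4 2.43-fold (1.28, adjusted p = 0.0129). Xcl1 (1.12), the axon guidance and immune ligand Sema7a (1.20), the interferon-induced gene Ifitm2 (1.38), the smooth muscle actin gene Actg2 (1.59, 3.01-fold, adjusted p = 0.000498) and Nqo1 (1.16, 2.23-fold) were also higher. Ptpn13 was 3.38-fold lower (-1.76, SE 0.201, adjusted p = 0.000418). Foxp3 was at 10.99 ± 0.104 against 11.34 ± 0.103 (SD, n = 4 each), a difference of -0.35 that was not called (SE 0.101, adjusted p = 0.0662), and Myc at -0.03 was not called either (adjusted p = 0.918).

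Others among the genes that fell most were Abcb1a, a drug efflux pump (-1.21), Nav2, a cytoskeletal regulator (-1.07), Vps37b (-1.05), the ubiquitin ligase Neurl3 (-1.05) and the receptor gene Olfr172 (-1.19). The myosin genes Myo3b (-1.04) and Myo1d (-1.03) fell as well. Of receptor genes 1.38% were called here, with a 95th percentile of 0.359 for the absolute log2 fold change, and 470 of the 539 called genes of other classes lay beyond it.

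Lists of mitochondrial genes had positive medians under rapamycin as well. Of 71 mitochondrial ribosome genes 18 rose and none fell, or 51 and none adjusted over the list alone (median 0.34, camera adjusted p = 2.49e-24; adjusted p = 0.263 with an estimated correlation). They included Mrpl36 (0.70), Mrpl52 (0.64) and Mrpl57 (0.56). Of 53 oxidative phosphorylation genes 10 rose and none fell, or 37 and none adjusted over the list alone (median 0.27, camera adjusted p = 6.16e-18; adjusted p = 0.263 with an estimated correlation), among them the complex I subunits Ndufb3 (0.53), Ndufc2 (0.46) and Ndufb8 (0.45). Without rapamycin Atg7-/- replicate 3, the array that stands apart, the medians of these lists were 0.27 and 0.22. Of 50 genes of Myc-linked ribosome biogenesis 8 rose and none fell, including Nhp2 (0.51), Noc4l (0.48) and Rrp9 (0.45), or 20 and none adjusted over the list alone (median 0.20, camera adjusted p = 4.28e-13; adjusted p = 0.263 with an estimated correlation).

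Of 23 effector cytokine genes 6 rose and none fell, or 15 and 1 adjusted over the list alone (median 0.62, camera adjusted p = 1.6e-08; adjusted p = 0.263 with an estimated correlation). Their median was 0.50 without rapamycin Atg7-/- replicate 3, whose mean score for the list was 0.419 against -0.447 to -0.236 on the other arrays of its group. The proteasome list had no called member of 38, 5 risers adjusted over the list alone and a median of 0.19 (camera adjusted p = 4.65e-07; adjusted p = 0.626 with an estimated correlation). Cytosolic ribosome genes had 2 risers of 60, Rpl27a (0.67) and Rpl6l (0.33), or 4 adjusted over the list alone (median 0.088, or from 0.0458 with the length trend removed to 0.147 with median centring; camera adjusted p = 0.000494; adjusted p = 0.418 with an estimated correlation). Suclg2, a succinyl-CoA ligase subunit (0.38), was the 1 riser of 21 TCA cycle genes, or 4 adjusted over the list alone (median 0.13, camera adjusted p = 0.00141; adjusted p = 0.626 with an estimated correlation). In the oxidative stress list 2 of 19 rose, Nqo1 and the mitochondrial superoxide dismutase Sod2 (0.35), or 5 adjusted over the list alone (median 0.14, camera adjusted p = 0.0102; adjusted p = 0.68 with an estimated correlation). Without rapamycin Atg7+/- replicate 1 or Atg7-/- replicate 3 the oxidative stress list lost the call (adjusted p = 0.0704 and 0.165), as it did without both outlying arrays (0.183). Cell cycle genes were not called, singly or as a list (camera adjusted p = 0.174). Of 26 Treg signature genes 1 rose, Lad1 (0.50), and 2 fell, Plagl1 (-0.94, adjusted p = 0.000418) and the transcription factor Ikzf4 (-0.45), or 3 and 4 adjusted over the list alone (median -0.0848, or from -0.158 without rapamycin Atg7-/- replicate 3 to -0.0261 with median centring; camera adjusted p = 0.0105; adjusted p = 0.626 with an estimated correlation). That list's call was lost without rapamycin Atg7+/- replicate 4 (adjusted p = 0.0631) or Atg7-/- replicate 1 (0.0928). Fry did not call the Treg signature (adjusted p = 0.217), proteasome (0.0503), TCA cycle (0.0664) or oxidative stress (0.14) lists. Among markers of CD8 T and NK cells, Nkg7 (0.94) and Cd8b1, a chain of the CD8 coreceptor (0.72), rose, and the list was not called. Its mean score ran from -0.143 to 0.0818 on rapamycin Atg7-/- arrays and from -0.319 to -0.214 on rapamycin Atg7+/- arrays. Conventional T cell markers were not called as a list either (camera adjusted p = 0.0627).

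In limma 543 genes were called between genotypes under rapamycin, 320 higher and 223 lower, of which 8 and 12 changed at least 2-fold; with each array centred on its median the split was 257 and 98. The balance turned to 115 and 172 without rapamycin Atg7-/- replicate 3, 105 and 118, and 41 and 54, without rapamycin Atg7+/- replicates 1 and 2, 152 and 187 without the 2 outlying arrays, 223 and 265 with all probe sets counted, 35 and 44 at an adjusted p under 0.01 and 6 and 14 with only the 2 groups in the fit. The arrays of the 2 genotypes did not overlap for 9.77% of genes, where chance gives 2.86%. The count was 95 without rapamycin Atg7+/- replicate 2, 223 and 255 without replicates 1 and 4 of that group, 287 and 269 without rapamycin Atg7-/- replicates 3 and 4, and 20 with only the 2 groups compared in the fit, which ended 28 of the 34 calls named here. Without rapamycin Atg7+/- replicate 2, 19 of the 34 lost the call: Ifitm2, Il4, Xcl1, Vps37b, Mrpl57, Ndufc2, Ndufb8 and Nhp2 only there (adjusted p = 0.0525 to 0.0774), and Olfr172, Ndufb3, Noc4l, Rrp9, Ikzf4, Lad1, Cd8b1, Suclg2, Sod2, Rpl27a and Rpl6l without at least 1 more rapamycin array (up to 0.0844, 0.117, 0.0844, 0.0844, 0.134, 0.0632, 0.063, 0.127, 0.129, 0.0927 and 0.147). Sod2 and Rpl6l lost it without any of 12 and 13 arrays, untreated ones among them.

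**Figure D4:**
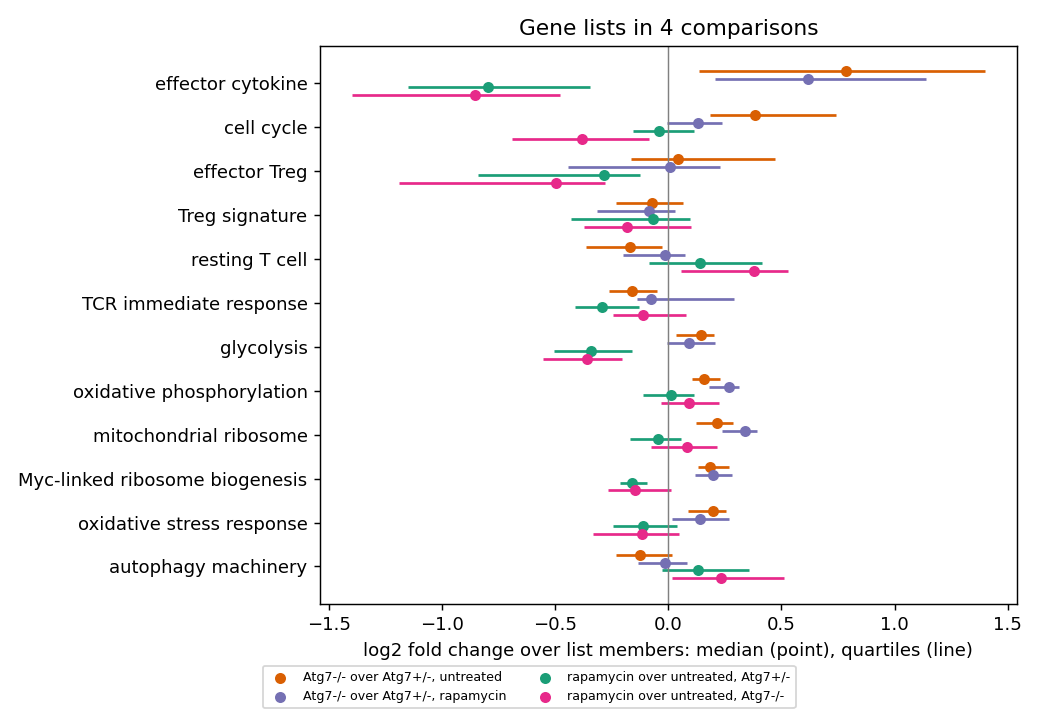
Log2 fold changes of 12 gene lists in 4 comparisons, with a point for the median over a list's members and a line from the lower to the upper quartile. Effector cytokine genes have medians of 0.79 and 0.62 between genotypes and of -0.80 and -0.86 for rapamycin, and cell cycle genes a median of 0.38 between untreated genotypes.

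Genotype effects without and with rapamycin come from different arrays, so their overlap is not raised by shared controls. Of the 527 genes called between untreated genotypes, 486 (92.2%) had the same sign under rapamycin, and 173 were called the same way, 81 higher and 92 lower, against 5.61 and 3.1 for independent lists. None was called the opposite way, and Pearson's r across the 527 genes, which are not independent replicates, was 0.804 with a slope of 0.531. For the 543 genes called under rapamycin, the slope of the untreated effect on theirs was 0.689. Choosing genes by 1 of the 2 effects can lower the slope of the other, so neither slope measures a weaker genotype effect. Il4, Ccl3, Nqo1, Ptpn13, Vps37b and Plagl1 were called in both. The 173 became 59 and 92 without rapamycin Atg7+/- replicates 2 and 4, 99 without rapamycin Atg7-/- replicate 4, 106, 105 and 103 without untreated Atg7+/- replicates 1, 3 and 4, 101 and 114 without untreated Atg7-/- replicates 1 and 3, and 84 with median centring. The overlap was not counted with only the 2 groups in the fit, where 20 genes were called between genotypes under rapamycin. Rapamycin effects were compared likewise: of 2370 genes called in Atg7+/- cells, 2310 (97.5%) had the same sign in Atg7-/- cells and 1519 were called the same way, 685 higher and 834 lower, against 89.3 and 151 for independent lists (r = 0.91 across genes). A labelling or hybridization difference between untreated and rapamycin arrays would give such agreement as well. Olfactory and vomeronasal receptor genes, which T cells are not known to use, had r = 0.831 between the 2 rapamycin effects. Of those called in Atg7+/- cells, 93% had the same sign in Atg7-/- cells.

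**Figure D5:**
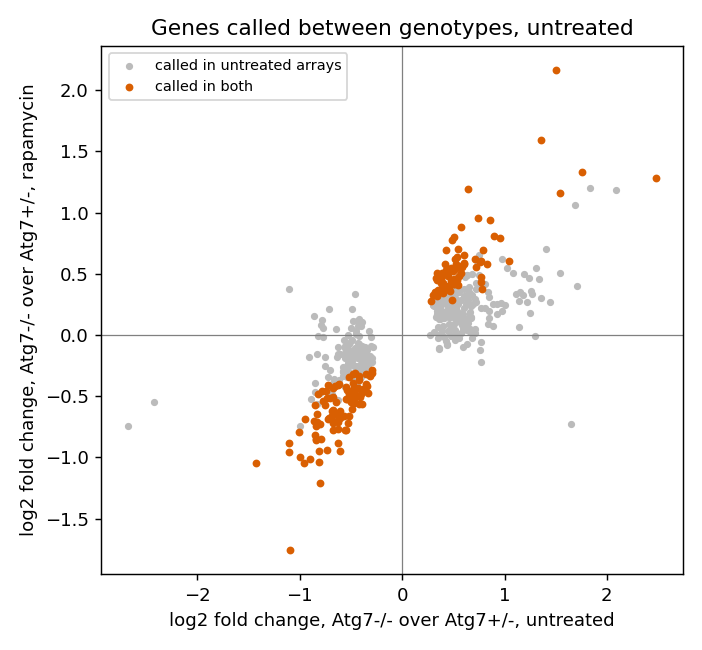
Log2 fold change between genotypes in untreated cells (horizontal) and under rapamycin (vertical) for the 527 genes called in untreated cells, 1 point per gene, coloured where the gene was called in both. The points follow a slope of 0.531, which choosing the genes by the horizontal effect can lower, and the 173 genes called in both lie in the quadrants of equal sign.

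Rapamycin in Atg7-/- cells was also set against the genotype effect in untreated cells. Ifng, Il13, Gzmb and Mki67, which were higher in Atg7-/- cells, fell with rapamycin, while Foxp3, which was lower, did not pass the test. Ifng and Il13 fell with rapamycin in Atg7+/- cells too, and no gene was called for the difference between the rapamycin effects. Opposite signs here are therefore not particular to cells without Atg7. Of the 527 genes 426 (80.8%) had the opposite sign and 260 were called the opposite way, against 53.3 for independent lists, while 28 were called the same way. The 260 became 147, 172 and 155 without untreated Atg7+/- replicates 1, 2 and 4, 150 and 170 without untreated Atg7-/- replicates 1 and 4, 168 with median centring and 445 with array weights. Both contrasts use the untreated Atg7-/- arrays with opposite signs, which gives opposition without any effect. The covariance across genes was -0.0265, against -0.00839 in 100 simulations without effects. With the 4 shared arrays split between the contrasts, 94 to 298 genes were called for genotype. Of these 72.8% to 87.7% had the opposite sign and 54 to 102 were also called that way for rapamycin. The covariance in the splits was -0.0209 to -0.0156. Pearson's r was -0.401, against -0.5 in the simulations and -0.29 to -0.195 in the splits.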

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

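Chosen only after the results were seen were the tests of a labelling difference and of conventional T cells, the use of fits without 1 array against outlying arrays, the splits in fits on 8 arrays, the brightness of receptor genes by their lowest group mean or their mean over all arrays and the sorting of draws by the labels they keep; removal of the gene length trend was chosen after the data were seen but before its outcome was.

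Olfactory and vomeronasal receptor genes, which T cells are not known to use, were called for rapamycin at 19.7% of 289 in Atg7+/- cells and 21.8% in Atg7-/- cells, against 0.692% and 1.38% between genotypes. Of the 88 receptor genes whose highest group mean lay above the 50th percentile, 4.551, 28.4% and 26.1% were called. With 2 choices less open to the change itself, the shares were 28% and 25.3% of the 75 with their mean over all arrays above it, and 24.6% and 22.8% of the 57 with all 4 group means above it. The calls were thus not confined to the dimmest receptor genes. Values near the floor are not excluded, since that cut lies under the median of the genes tested on every array (lowest 5.518). A labelling or hybridization difference between untreated and rapamycin arrays is a candidate explanation: 93% of the receptor genes called in Atg7+/- cells had the same sign in Atg7-/- cells, and the first component of all receptor genes ran from -4.64 to -3.26 in untreated and from 3.1 to 4.48 in rapamycin arrays. No batch label is given, so such a difference cannot be told apart from an effect of rapamycin, which stays open and untested. The same difference may also have moved part of the other genes called for rapamycin, of which 136 of 2313 and 138 of 3284 changed by more than the 95th percentile of receptor genes.

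The 71 mitochondrial ribosome genes had a median log2 fold change of 0.34 between genotypes under rapamycin, with 18 called higher in Atg7-/- cells, though the named ones lost the call with only the 2 groups in the fit. A trend with gene length as the whole cause is argued against, since after it was removed the median was 0.295 (camera adjusted p = 1.15e-23). The outlying array, rapamycin Atg7-/- replicate 3, does not account for all of it either, since the median without it was 0.266 (camera adjusted p = 9.26e-20). With a correlation estimated from the data the list was not called (adjusted p = 0.263, against 0.0022 or less in its other alternatives), so a set of arrays in which these genes move together for another reason stays open. An effect of Atg7 loss on mitochondrial protein genes may be the source, as a hypothesis found and tested on the same data.

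Foxp3 was lower in untreated Atg7-/- cells (-0.40), where 10 of 23 effector cytokine genes were higher and 1 lower (median 0.79; adjusted p = 0.131 with an estimated correlation). Conventional T cells carried through the sort would need to be 24.4% of the cells to lower Foxp3 this far, if they expressed none of it. Of the other 25 Treg signature genes 22 lay above the Foxp3 change, with a median of -0.07 and an interquartile range of 0.274. This cannot decide the matter, since signature genes that stimulated conventional T cells also express would fall less than Foxp3. No such cells were measured, and the purity of the sort on the Foxp3 reporter was not available here. Mean scores of the conventional T cell markers were 0.258 to 0.393 on untreated Atg7-/- arrays. They were 0.0365 to 0.151 on untreated Atg7+/- arrays, a difference in the direction that more such cells would give. This cannot decide it either, since genes of this list such as Lat are also expressed in Treg cells. The filter on dim genes, which all 11 passed, does not tell the sources apart. The brightest of the 11 were Lat (11.07 in Atg7+/- cells, difference 0.17) and Cd3e (11.06, 0.11). No single array accounts for the cytokine genes, whose median was at least 0.756 in the fits without 1 array. Other cells carried through the sort, and reduced Foxp3 expression within Treg cells, may each contribute and were not told apart. Markers of CD8 T and NK cells, not called as a list, had mean scores of 0.186 to 0.339 on untreated Atg7-/- arrays. On untreated Atg7+/- arrays their scores were -0.0647 to 0.188.

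Chance was tested in 4 of the 5 comparisons by splitting their 8 arrays in other ways. The other 8 arrays kept their groups in the same fit. Of 35 splits only the real split gave as many called genes: 527 between untreated genotypes against 1 in the highest other split, 2370 and 3347 for rapamycin against 0 and 7, and 543 between genotypes under rapamycin against 39. In fits on the 8 arrays alone the real counts were 708, 2776, 2247 and 20, in the same order, against 0, 1, 0 and 0 in the highest other split. With 35 splits the test can reach no further than 1 in 35 per comparison, so chance is argued against at that level and not excluded. The splits also take arrays as exchangeable, which shared handling of same-numbered rapamycin arrays would break. For the difference of the rapamycin effects limma called 0 genes, with 1052 at an unadjusted p under 0.05, so that all 100 draws of treatment labels within the genotypes, the real labels included, give at least as many by construction and say nothing about chance. The highest draw called 336 genes; it was the 1 draw that kept the real labels of 3 more rapamycin arrays in 1 genotype than in the other, the 33 and 46 draws in which that difference was 0 and 1 called none, and of the 19 in which it was 2, 3 called genes, at most 11.

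Single arrays stood apart from the other 3 of their group, by a gap beyond Dixon's 95% limit for 4 values, in 19 of 400 groups of named gene values; chance gives about 1 in 20. In untreated Atg7+/- cells these were Ccl3 (6.66), Foxp3 (11.32), H2ac15 (8.39) and Mir188 (3.20) on replicate 2, Il4 (6.11) and Kif11 (5.39) on replicate 1, and Psmd5 (6.72) and Psph (6.28) on replicate 4. In untreated Atg7-/- cells they were Atg13 (5.85) on replicate 1, Dnah7a (3.64) and Slc16a3 (5.68) on replicate 2, and Lad1 (9.10), Myc (10.74), Pkm (10.42) and Themis (7.54) on replicate 4. Under rapamycin they were Herpud1 (6.83) and Trappc6a (6.91) on Atg7+/- replicate 1, Myo3b (4.61) on Atg7-/- replicate 1 and Ndufb3 (7.86) on Atg7-/- replicate 3.

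Mean scores of gene lists, as log2 deviations from each gene's mean, stood apart in the same way on single arrays in 6 of 136 groups, where chance gives about 1 in 20. The scores were 0.126 for ER stress genes on rapamycin Atg7-/- replicate 3, -0.630 for effector cytokine genes and -0.171 for conventional T cell markers on rapamycin Atg7+/- replicate 3, and -0.216 for plasma cell markers on untreated Atg7-/- replicate 3. Erythroid markers scored 0.423 on untreated Atg7-/- replicate 4 and -0.273 on rapamycin Atg7-/- replicate 4. Within that group replicate 3, inside Dixon's limit, had the highest scores for B cell (0.237), macrophage and monocyte (0.441), neutrophil (0.466) and conventional T cell (0.257) markers, as it had for effector cytokine genes (0.419).

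The rapamycin effects of 8 lists differed between genotypes by camera's test of the difference, as Atg7-/- minus Atg7+/-, none of them with an estimated correlation (adjusted p = 0.131 for cell cycle genes, 0.862 or more for the others) and none by fry (0.0744 or more). Median differences were -0.29 for cell cycle, -0.284 for effector Treg, -0.258 for macrophage and monocyte, 0.147 for early T cell receptor response, 0.127 for resting T cell, 0.111 for autophagy, 0.109 for mitochondrial ribosome and 0.0902 for oxidative phosphorylation genes. The cell cycle, effector Treg and mitochondrial ribosome lists kept the call in every fit without 1 array, and the other 5 did not. Over all alternatives the medians ran from -0.426 to -0.228 for cell cycle, from -0.33 to -0.148 for effector Treg and from 0.0452 to 0.17 for mitochondrial ribosome genes. Oxidative phosphorylation genes lost the call without rapamycin Atg7+/- replicate 2 (0.0579, adjusted p = 0.0975) or Atg7-/- replicate 3 (0.0396, 0.156), and early T cell receptor response genes without untreated Atg7-/- replicate 4 (0.077, 0.0601) or rapamycin Atg7+/- replicate 1 (0.0548, 0.0714). Autophagy genes lost it without any of 7 arrays (lowest median 0.0602 without rapamycin Atg7+/- replicate 1; adjusted p up to 0.152) and resting T cell genes without any of 7 (lowest 0.0892 without the same array; up to 0.202). Macrophage and monocyte markers lost it without any of 8, at -0.116 without rapamycin Atg7+/- replicate 3 (adjusted p = 0.401) and -0.0915 without rapamycin Atg7-/- replicate 1 (0.195). Quantile normalization also ended the calls of autophagy and resting T cell genes (adjusted p = 0.0939 each) and of oxidative phosphorylation genes and macrophage and monocyte markers (0.0584 each), and the stricter filter on dim genes that of autophagy genes (0.0653). Without the 2 outlying arrays autophagy (0.13), resting T cell (0.399) and early T cell receptor response genes (0.11) lost it.

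Of the 12776 tested probe sets without a single gene symbol, which enter no comparison, limma called 126 between untreated genotypes, 1552 and 1935 for rapamycin in Atg7+/- and Atg7-/- cells, and 184 between genotypes under rapamycin.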

How the results depend on the processing

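Leaving out 2 outlying arrays, leaving out receptor and small RNA genes, the receptor covariate, removing the length trend, and most alternatives for the overlap counts were chosen only after the data were seen.

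Counts of called genes kept within 1.5 times of the reported ones in 64 of 84 alternatives other than leaving out 1 array. The 64 include all alternatives for the difference of the rapamycin effects, where the count stayed at 0 and stricter thresholds could give nothing else. Between untreated genotypes (527) the counts outside that range were 318 with median centring, 974 with array weights, 40 at 2-fold or more, 161 at an adjusted p under 0.01 and 298 with the receptor covariate. For rapamycin in Atg7+/- cells (2370) they were 106 at 2-fold, 913 at 0.01 and 3675 with all probe sets counted, and in Atg7-/- cells (3347) 148 at 2-fold and 1633 at 0.01. Both rapamycin counts became 0 with the receptor covariate, as did the 1519 genes called in both and the 260 called against the genotype effect; that covariate separates the treatments completely, so these zeros follow from its construction. Between genotypes under rapamycin (543) they were 820 with the stricter filter on dim genes, 355 with centring, 886 with trend and robust variance, 20 with only the 2 groups in the fit, 20 at 2-fold, 79 at 0.01, 339 without the outlying arrays (untreated Atg7-/- replicate 4 and rapamycin Atg7-/- replicate 3) and 250 with the receptor covariate. Genes called the same way between genotypes without and with rapamycin (173) became 84 with centring, 260 with trend and robust variance and 76 with the receptor covariate, and the 260 opposed genes became 168 with centring and 445 with array weights. Stricter thresholds lower the counts by construction; otherwise the cause was not tested.

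Without 1 array the counts ran from 282 to 695 (highest without rapamycin Atg7-/- replicate 3), 1554 to 2785, 2513 to 3414, 95 to 790 and 0 to 1 for the 5 comparisons in the order of untreated genotypes, rapamycin in Atg7+/-, rapamycin in Atg7-/-, genotypes under rapamycin and the difference of effects. The overlap counts ran from 59 to 201, from 1122 to 1806 and, for the opposed genes, from 147 to 338. With replicate number as a block the counts were 529, 2492, 3491, 592 and 0, and the overlap counts 175, 1607 and 264. The labels give no pairing by number. Deviations of same-numbered arrays correlated above 0.1 in 6 of 24 pairs, 3 of them among the 4 pairs between the rapamycin groups (0.24, 0.192 and 0.358; the fourth -0.0658), and 8 of 16 arrays correlated best with their own number, where chance gives about 4. Shared handling of rapamycin arrays is therefore not excluded. Under the block only the amino acid list for rapamycin in Atg7+/- cells (adjusted p = 0.0534, and up to 0.535 in its other alternatives), Dkc1 between untreated genotypes and Rpl6l between genotypes under rapamycin lost the call among lists called and genes named.

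Of 216 values of named genes 194 were called, and 1 of these changed sign: Rplp0 for rapamycin in Atg7+/- cells, at -0.00895 with the mean of its probe sets. The other signs that turned belong to values near 0 that were not called. Myc between untreated genotypes was 0.00359 without the outlying arrays and from -0.123 to 0.00359 without 1 array. Under rapamycin it was 0.0302 with centring, 0.0168 without the outlying arrays and from -0.0684 to 0.0168 without 1 array, with 0.00777 without rapamycin Atg7+/- replicate 2. Atg7 for rapamycin in Atg7-/- cells ran from -0.0103 to 0.254 without 1 array. Its difference of effects was 0.033 with centring, 0.0144 without the outlying arrays, 0.0517 without untreated Atg7-/- replicate 3 and from -0.139 to 0.125 over all such fits. Differences of effects ran from -0.0493 to 0.12 for Foxp3 and from -0.0321 to 0.102 for Myc, both lowest without untreated Atg7-/- replicate 4. The cause of these turns was not tested. Besides these, alternatives ended 127 calls and made 3 among values of named genes, and leaving out 1 array ended 208 and made 2, among them Foxp3 between genotypes under rapamycin (adjusted p = 0.0182 to 0.216 over its alternatives). List calls were lost 97 times in other settings, among them every call with an estimated correlation, and 52 times without 1 array; no called list changed sign except mitochondrial ribosome genes for rapamycin in Atg7-/- cells, at -0.00351 without the outlying arrays, where it was not called. Signals near the floor limit the dim genes left out, and 4 arrays per group limit changes near log2 0.5, of which the fit recovered 52% to 58% in simulations.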

Other observations

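All tests of gene families here were chosen after the results were seen, and the genes named here from the fixed lists were chosen after their values were seen.

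Treg signature genes were called in both directions between rapamycin and untreated cells. Nrp1, a surface receptor of thymus-derived Treg cells, fell by 0.85 in Atg7+/- cells and by 0.80 in Atg7-/- cells, the integrin gene Itgae, which holds T cells at epithelia, by 0.79 and 0.85, and Sytl2, a vesicle transport gene, by 0.79 and 1.04. Socs2, a suppressor of cytokine signalling, rose by 0.88 in Atg7-/- cells, or by 0.48 with the mean of its probe sets and 0.51 without the 2 outlying arrays. Of these values only that of Sytl2 in Atg7-/- cells lay beyond the 95th percentile of receptor genes (0.921 in Atg7+/- and 0.994 in Atg7-/- cells). Of 26 signature genes 2 rose and 7 fell in Atg7+/- cells and 5 rose and 9 fell in Atg7-/- cells, or 2 and 8, and 5 and 10, adjusted over the list alone, and neither list was called (camera adjusted p = 0.233 and 0.132). ER stress genes showed 7 fallers of 24 in Atg7+/- cells and 6 in Atg7-/- cells, or 9 fallers and 1 riser, and 7 and 1, adjusted over the list alone, with Herpud1 at -0.51 and -0.47 and the chaperone Hyou1 at -0.39 and -0.40. The chaperone Dnajb9 rose by 0.96 in Atg7-/- cells (0.63 without the 2 outlying arrays), also within that percentile, and the ER stress list was not called in either genotype (camera adjusted p = 0.05 and 0.35).

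Gene families formed from shared symbol stems, 245 in number, were tested for their share of called genes in 1960 exact Fisher tests. Zinc finger genes (Zfp) were called higher for rapamycin at 18.6% of 328 in Atg7-/- cells, against 8.64% of other genes (adjusted p = 1.09e-05), and at 11.6% against 5.92% in Atg7+/- cells (adjusted p = 0.024). Between untreated genotypes 4 of 8 complex I assembly factor genes (Ndufaf) were higher (adjusted p = 0.00241) and 5 of 37 Zbtb transcription factor genes lower (adjusted p = 0.0282) in Atg7-/- cells. For rapamycin in Atg7+/- cells, 7 of 16 tyrosine phosphatase genes (Ptpn), 5 of 8 Schlafen genes (Slfn) and 5 of 8 tumour necrosis factor ligand genes (Tnfsf) were lower (adjusted p = 0.0282 each). With each array centred on its median the counts called in these directions were 60 and 25 Zfp genes, 2 Ndufaf, 4 Zbtb, 7 Ptpn, 5 Slfn and 5 Tnfsf genes, and with quantile normalization 55, 31, 3, 5, 7, 6 and 5. Families with similar sequences can share probes, so their members are not independent.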
